A study of Mus musculus with 10 samples.

How the data were processed

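The data are 10 libraries of polyadenylated RNA from CD31-positive cells sorted from mouse brain, made with a kit that does not mark strand, per the labels' protocols. Reads from overlapping or antisense genes therefore stay mixed. Mice of strain C57BL6 received control diet or PLX5622 diet (1200 ppm) for 1 month, with 3 males and 2 females on each. The titles call the replicates biological, and group, sex and replicate number were taken from them.

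Reads were aligned with STAR 2.7.10a to mm39 and counted with featureCounts of Subread 2.0.1, and DESeq2 1.32.0 was run in R 4.1.0, per the submitters' processing notes. The authors deposited TPM (reads divided by gene length and scaled to the same total in each library) for 26264 genes per library. TPM keeps no depth by itself. The authors also deposited a DESeq2 table of 19474 genes with a mean normalized count, log2 fold change, its standard error, a test statistic, p-value and adjusted p-value per gene. The log2 fold changes in the authors' table run from control to PLX5622. The test statistic and the mean count in the deposited table were treated as scores. The model formula behind the table is not given in the sources used here. Gene symbols are those of the files. The annotation at hand belongs to another genome build, so no coordinates are given.

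Whole reads were recovered after the files were seen, by solving for the factors that turn TPM and the authors' mean counts into whole numbers. All recovered values (100.0%) were whole within 0.05 reads, and the authors' mean counts were met with a largest relative error of 7.5e-15. These reads give the depth of each library, 26.4 to 61.5M, the ratios of pooled reads, and an added alternative test. They are recovered values, and the main test uses TPM.

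The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with trended variance, a model of sex plus diet, and genes at TPM of at least 1 in at least 5 of 10 libraries (12751 genes). Tests were two-sided with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes on this scale understate those of low genes. Sex, and the interaction of sex and diet, were tested in the same way. Of 41 gene lists fixed by hand (pathways, cell types and label checks), 39 had at least 3 tested members and were tested with limma's camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry beside it. The erythrocyte and X inactivation lists had too few tested members. The list levels given per library are means over members of log2(TPM + 1) centred on each gene's mean. Sums of TPM were compared by exact permutation over 252 splits, which ignored sex. Tools were numpy 2.4.6, pandas 2.3.3 and Python 3.11.15.

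The design, lists, rule for named genes and 29 of the alternative settings were set before the data were examined. The rule took the 12 largest changes in each direction among called genes whose diets did not overlap, passing over predicted genes. From each list it took up to 4 called members, or the 2 most abundant where none was called, then 8 fixed genes and the 5 largest sex differences in each direction. Not every gene that the rule takes is named in the text, and the values of some genes are not reported here. Hmgcs1, C1qa, C1qb, Cd68, Irf8, Irf7, Abca1, Mylip, Apoe, Fasn, Fads1, Scd1, Cav2, Nkd1, Nkd2, Foxf2, Vwf, Lcn2, Vcam1 and Ackr1 were named after their values were seen. These settings changed the scaling, pseudocount (0.1 and 5), filter, variance model, weights, covariates, pairing, samples, threshold and list test, and left out each library in turn. Another 6 were added after seeing the data: voom on recovered reads with either filter, a batch term for the last-numbered samples, and 3 fits without a pair of libraries.

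The test was checked on simulated values for the same 12751 genes with the real means and residual spread, drawn independently between genes, with 200 genes changed. It called 36% of 50 genes changed 1.25-fold, 66% at 1.5-fold, 88% at 2-fold and 100% at 3-fold, all in the right direction, and 8 unchanged genes. Of 10 random lists of 18 genes shifted by 0.2 on the log2 scale, camera called 10, and it called 1 of 30 unshifted lists. Genes in real lists vary together, which this simulation leaves out, so the estimated correlation is given beside each list call.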

Results

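Transcript levels were measured in endothelial cells sorted from the brains of C57BL6 mice that had eaten control diet or PLX5622 diet for 1 month. PLX5622 blocks CSF1R, the receptor on which microglia depend for survival, and was given at 1200 ppm. The series asks how loss of microglia affects brain vessels. Cells carrying CD31, a surface protein of endothelium, were sorted from brain without meninges, cerebellum and olfactory bulbs. The 10 libraries came from 3 male and 2 female mice on each diet. Whole reads recovered from the deposited values gave 26.4M to 61.5M reads (M, mega) per library, with a median of 31.2M. Control male 2 was the deepest at 61.5M, and the other control libraries held 28.1 to 36.1M.

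Most microglial transcripts were far lower in the PLX5622 libraries. Csf1r, the receptor the compound blocks, stood at 10.8 ± 7.70 TPM on control diet and 0.173 ± 0.184 TPM on PLX5622 (SD, n = 5 each). Over all reads of a diet this was 2775 reads against 33. Ratios of pooled reads were scaled to the total depth, 193.4M reads on control diet and 146.6M on PLX5622. For Csf1r the scaled ratio was 63.7-fold, with a 95% counting interval of 45.3 to 92.8. PLX5622 male 2 held 17 of the 33 Csf1r reads, and without it the ratio was 106 (65.3 to 186). Cx3cr1, the fractalkine receptor of microglia, had 840 reads on control diet and 0 on PLX5622. With the same scaling it was at least 212-fold lower, against a floor of 3 reads over the group. Tmem119, a microglial surface protein, had 436 reads against 5, and P2ry12, a microglial purine receptor, 725 against 46. The complement genes C1qa and C1qb had 865 against 2 reads and 1099 against 8. Not all of the list was lower, since Cd68, a lysosomal protein of phagocytes, had a ratio of 0.996 and Irf8, a myeloid transcription factor, 0.973, with control diet over PLX5622. Intervals and floors cover counting error only.

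Of the 28 microglial genes fixed as a list, 9 passed the filter on low values, 1 fell, none rose and 8 did not pass the limma test over all genes. Adjusted over the list alone, 7 were lower. The median log2 fold change of the 9 was -1.05, with a limma camera adjusted p of 1.94e-07, and adjusted p = 0.21 with an estimated correlation. The TPM summed over the list was 228 ± 88.9 on control diet and 95.8 ± 8.65 on PLX5622 (SD, n = 5 each, two-sided exact permutation p = 0.0317). Control female 1 stood apart from the other controls, with Csf1r at 0.07 TPM from 3 reads and a list sum of 99.0 TPM. Without it the median log2 fold change of the list was -1.31. The median was -2.97 with a mean TPM of at least 5, -3.83 with voom on recovered reads with a mean of at least 10, -0.45 with a pseudocount of 5 and -0.43 in females only, with the list called in each (limma camera adjusted p up to 0.0304).

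**Figure D1:**
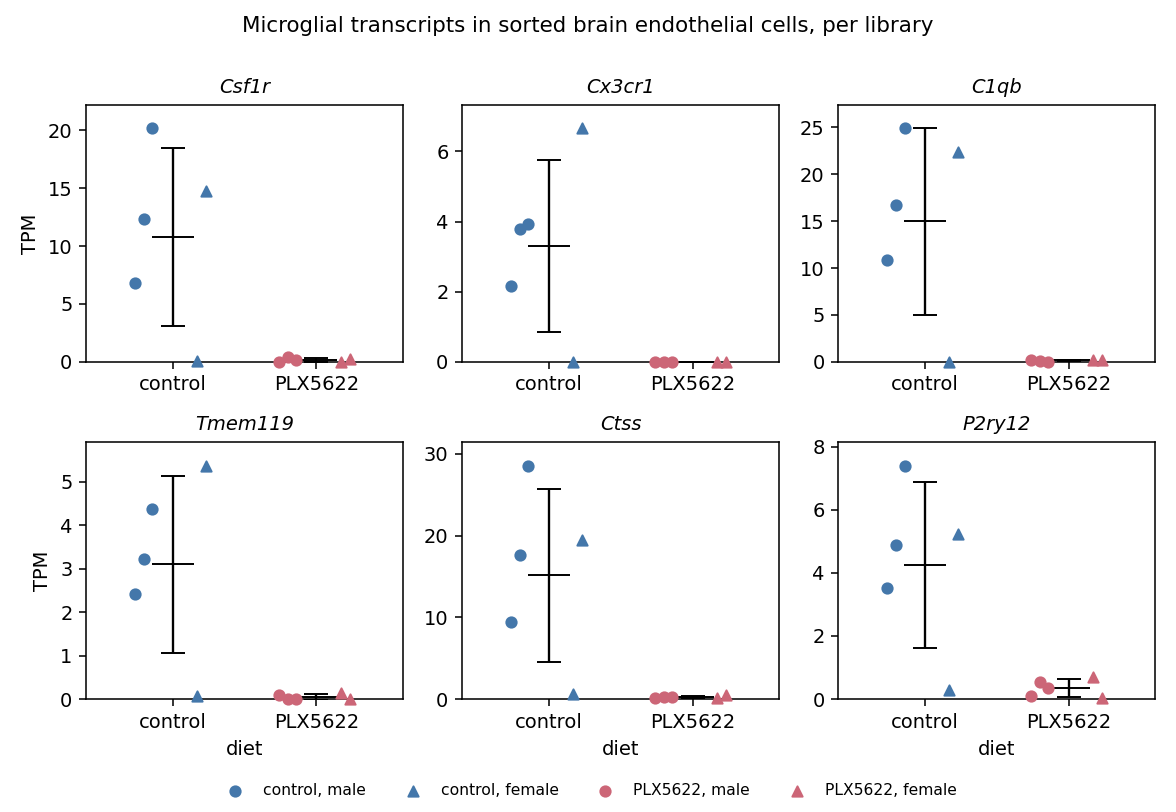
TPM of 6 microglial genes in each of the 10 libraries (y axis, TPM) by diet (x axis), with circles for males and triangles for females, and bars for the mean and SD of 5 libraries. Csf1r reached 20.2 TPM on control diet and 0.46 TPM on PLX5622, and control female 1 lay at 0.07 TPM.

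PLX5622 diet raised genes of cholesterol synthesis and its regulation in the sorted cells. Sqle, which makes squalene epoxide, rose from 14.5 ± 1.06 to 28.1 ± 4.54 TPM (SD, n = 5 each), a log2 fold change of 0.90 ± 0.11 (SE, limma adjusted p = 0.00882). Fdps, the farnesyl diphosphate synthase, rose by 0.74 ± 0.09. Insig1, a sterol-sensing membrane protein that restrains the pathway, rose by 0.64 ± 0.06. Angpt2, an angiopoietin that antagonises Tie2 signalling, rose from 17.0 ± 1.89 to 31.1 ± 4.14 TPM.

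In all, 17 of 12751 tested genes passed the limma test, 12 higher and 5 lower on PLX5622, and 1059 genes had an unadjusted p under 0.05. Other higher genes were Cyp51, Fdft1, Msmo1 and Sc5d, which are enzymes of sterol synthesis, Srebf2, the transcription factor that drives that pathway, and Pcyt2, an enzyme of phosphatidylethanolamine synthesis. Their log2 fold changes ran from 0.39 for Pcyt2 to 0.71 for Cyp51. The lower genes included Rgs10, a regulator of G protein signalling, at -1.46, the small nucleolar RNA Snord16a at -1.09, Abcg1, a sterol exporter, at -0.86, and Scn3b, a sodium channel subunit, at -0.69. Snord16a is a short RNA that lies within another gene, so its value in unstranded libraries of polyadenylated RNA is uncertain, and the authors' deposited table gave it an adjusted p of 0.217 in DESeq2. All 5 libraries of each diet lay apart from the other diet for all 17 genes. That held for 1.8% of tested genes, where chance gives 0.79%.

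Which genes passed depended on single libraries. The count was 7 without control male 1 (6 higher, 1 lower), 5 without control male 2 (5 and 0), 9 without control female 2 (8 and 1), 9 without PLX5622 female 1 (7 and 2), 9 without PLX5622 male 1 (6 and 3) and 6 without PLX5622 male 2 (6 and 0). Without control female 1 it was 14, of which 7 were higher and 7 lower, and 10 were shared with the 17. Sqle, Angpt2, Fdps and Insig1 passed limma's threshold in each of the 10 fits that left out 1 library, and Sc5d in none of them. Fdft1 missed it without control male 2 (limma adjusted p = 0.0538), and Rgs10 without control male 1, control male 2 or PLX5622 male 2 (limma adjusted p = 0.0503, 0.0613 and 0.0502). Abcg1 passed only without PLX5622 female 2, with limma adjusted p up to 0.157 in the other 9 fits. Pcyt2 and Scn3b missed it in 9 fits, Srebf2 in 8, Snord16a in 7, and Cyp51 and Msmo1 in 6. All 17 genes kept their sign in each fit, which follows from diets that did not overlap. The count was 0 without both PLX5622 male 2 and control male 2, a pair chosen after its values were seen, with 761 genes at an unadjusted limma p under 0.05.

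**Figure D2:**
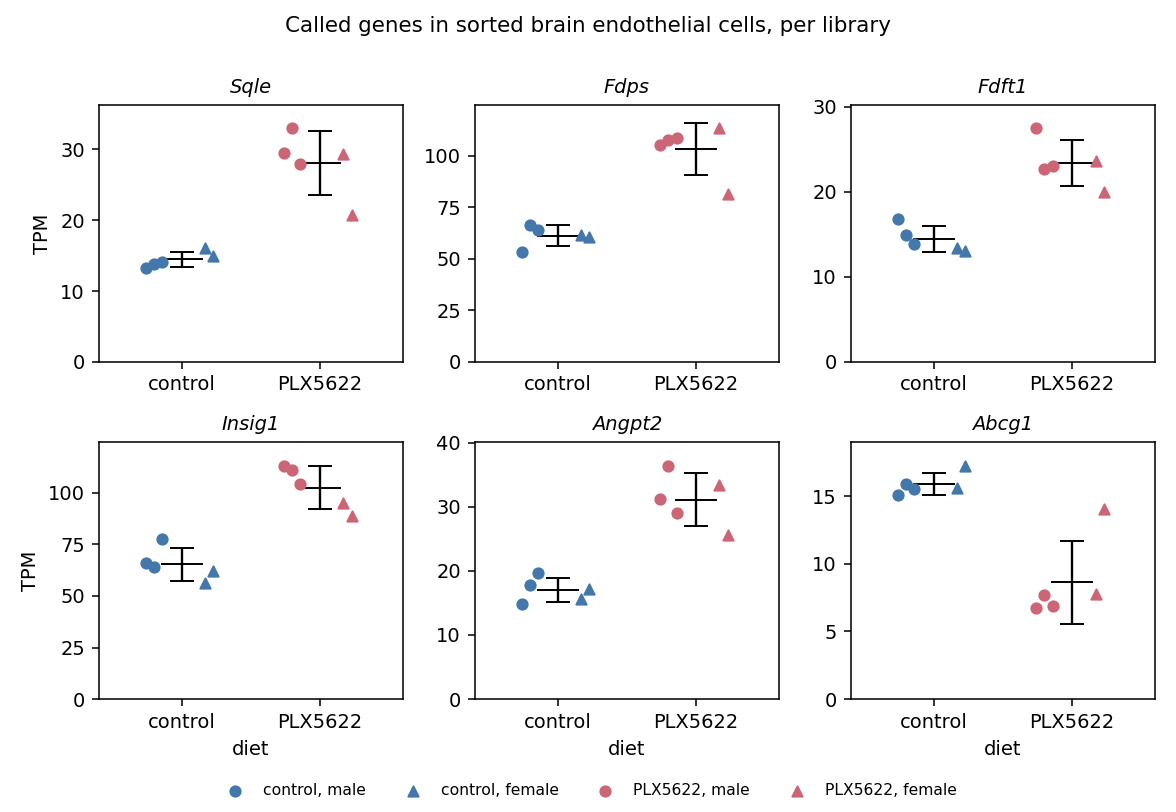
TPM of 6 genes past the limma threshold in each of the 10 libraries (y axis, TPM) by diet (x axis), with circles for males and triangles for females, and bars for the mean and SD of 5 libraries. Sqle averaged 14.5 TPM on control diet and 28.1 TPM on PLX5622, while Abcg1 averaged 15.9 and 8.63 TPM, with PLX5622 female 2 at 14.1 TPM.

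The cholesterol biosynthesis list rose as a group. Of its 19 tested members 7 rose, none fell and 12 did not pass over all genes. Adjusted over the list alone, 15 were higher, among them Hmgcs1, an early synthase of the pathway, at 0.41. Altogether 18 members lay above 0, with a median log2 fold change of 0.35. The limma camera adjusted p was 1.75e-28, and adjusted p = 0.101 with an estimated correlation. In limma's fry, which asks whether members move on balance in a single direction, this was the only list called among 39, at an adjusted p of 0.0135. PLX5622 female 2 showed a smaller shift, with a mean centred log2 level of the list of -0.06, against 0.21 to 0.32 in the other PLX5622 libraries and -0.25 to -0.19 in the controls.

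Among 13 tested genes of cholesterol uptake and sensing, 3 rose, among them Insig1 and Srebf2, and 10 did not pass. Adjusted over the list alone, 4 were higher and 1 lower. Members went both ways, with 8 above 0, 5 below 0 and a median log2 fold change of 0.06. Camera called the list higher (limma adjusted p = 0.00048), with adjusted p = 0.231 with an estimated correlation. Among 14 genes of cholesterol efflux, Abcg1 fell and 13 did not pass limma over all genes, and the list was not called (limma camera adjusted p = 0.422). The efflux list had 3 lower and 1 higher adjusted over the list alone. These were Abcg1, the exporter Abca1 at -0.55, Mylip, an E3 ubiquitin ligase, at -0.33, and the apolipoprotein gene Apoe at 0.30. None of 18 fatty acid synthesis genes passed limma over all genes, while the authors' deposited table called Fasn and Fads1 higher and Elovl5 lower (DESeq2 adjusted p = 6.48e-05, 0.0374 and 0.010). Fasn and Fads1 were higher and Scd1 and Elovl5 lower adjusted over the list alone, at 0.52, 0.29, -0.73 and -0.33. That list was not called (limma camera adjusted p = 0.435).

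**Figure D3:**
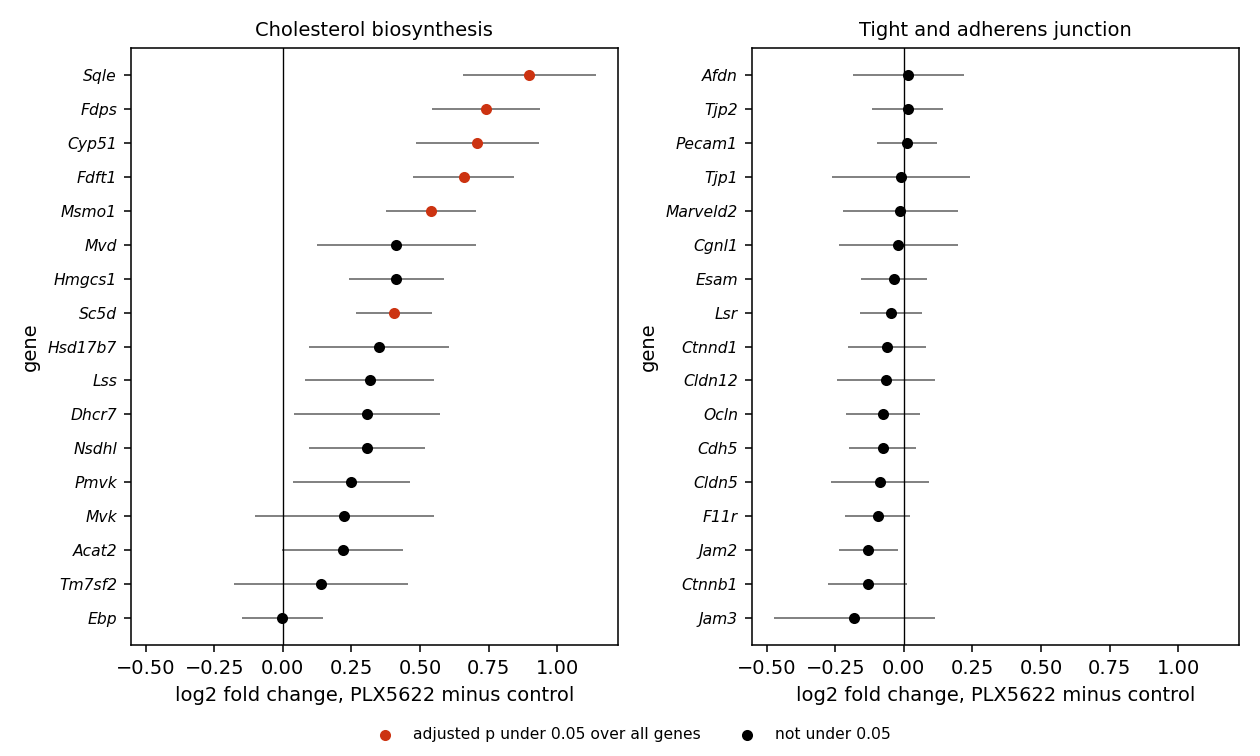
Log2 fold change of PLX5622 against control diet with its 95% confidence interval (x axis) for genes (y axis) of cholesterol biosynthesis, left, with some members not drawn, and tight and adherens junctions, right. Red points passed the limma threshold over all genes, which 6 of the 17 drawn did on the left and 0 of 17 on the right.

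Single genes of the blood-brain barrier were not called between the diets. Cldn5, the main claudin of brain endothelial tight junctions, stood at 7773 ± 423 TPM on control diet and 7338 ± 691 TPM on PLX5622 (SD, n = 5 each). Its log2 fold change was -0.09, with a 95% confidence interval of -0.26 to 0.09. Pecam1, which encodes CD31, was at 0.01 (-0.10 to 0.12), or -0.0096 with quantile normalization. None of 17 tight and adherens junction genes passed limma over all genes, nor adjusted over the list alone. Their median was -0.06 and the limma camera adjusted p 0.0765, which became 0.022 without control female 1 and 0.0444 without PLX5622 female 2. It was also under the threshold with quantile normalization (limma adjusted p = 0.0464), in males only (0.0258) and without both of these female libraries (0.0227). None of 30 transporter genes passed either, and the limma camera adjusted p was 0.94. Slc2a1, the glucose transporter of the barrier, was at 0.15 (-0.03 to 0.33) and Slco1a4, an organic anion transporter, at -0.11 (-0.25 to 0.03). In a simulation with 200 of 12751 genes changed, 66% of changes at 1.5-fold were called in this design, and 36% at 1.25-fold. Only 17 genes passed in the data, which makes the adjustment stricter than in that simulation. These shares are therefore likely too high for the data, and changes of this size or smaller could be missed.

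Camera called 2 further barrier lists lower. For caveolae and transcytosis the limma adjusted p was 0.00318 (adjusted p = 0.21 with an estimated correlation), with 13 of 14 members below 0 and none past limma's threshold over all genes. Adjusted over the list alone, 3 were lower, among them Cav1 and Cav2, which encode caveolins, at -0.37 and -0.33. Cavin2 was at -0.01, and at 0.0041 with median-of-ratios scaling. The mean centred log2 levels of the list overlapped between the diets, at -0.308 to 0.245 in control libraries and -0.291 to 0.0952 on PLX5622. For Wnt signalling the limma adjusted p was 0.0188 (adjusted p = 0.468 with an estimated correlation), with a median of -0.10 and none of 22 past limma's threshold over all genes. Adjusted over the list alone, the Wnt antagonist Nkd1, at -0.32, and the transcription factor Foxf2, at -0.19, were lower and Nkd2 higher at 0.51. The authors' deposited table called Nkd1 lower and Nkd2 higher over all genes (DESeq2 adjusted p = 0.00357 and 0.0428). The Wnt call was lost without control male 3, control female 2, PLX5622 female 1 or PLX5622 male 3, at limma adjusted p of 0.0604, 0.076, 0.051 and 0.215.

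Interferon response genes were called higher as a list. Of 29 members 27 lay above 0, with a median log2 fold change of 0.21 and a limma camera adjusted p of 9.50e-16, and adjusted p = 0.21 with an estimated correlation. None passed limma over all genes, and 15 were higher adjusted over the list alone, among them Irf7, a transcription factor of the response, at 0.57, and Bst2, an antiviral membrane protein, at 0.33. The authors' deposited table called Irf7 higher over all genes (DESeq2 adjusted p = 0.0022). Control males lay lowest, with mean centred log2 levels of -0.42 to -0.14, against 0.07 and 0.23 in control females, -0.04 to 0.07 in PLX5622 males and 0.17 and 0.27 in PLX5622 females.

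The leukocyte adhesion list was called higher (limma camera adjusted p = 0.00109, and adjusted p = 0.214 with an estimated correlation), with none of 17 members past limma's threshold over all genes or adjusted over the list alone. The authors' deposited table called its member Lcn2 higher over all genes (DESeq2 log2 fold change 3.40, adjusted p = 0.0141). PLX5622 male 2 stood far above the other libraries of its diet. It held Lcn2, an inflammation-induced lipocalin, at 92.5 TPM against 5.0 to 14.4, Vcam1, a leukocyte adhesion molecule, at 104 against 40.4 to 47.0, and Ackr1, a chemokine-binding receptor of venules, at 80.5 against 0.473 to 4.68. Without it the log2 fold changes of Lcn2, Vcam1 and Ackr1 went from 2.07, 0.35 and 1.53 to 1.34, 0.09 and 0.55, none of them called in limma with or without it. The venous list, which shares Lcn2, Vcam1 and Ackr1 with it, was called higher at a limma adjusted p of 0.00945 (adjusted p = 0.468 with an estimated correlation). Of its 14 members 2, Vwf and Lcn2, were higher adjusted over the list alone. Both lists stayed called in each fit that left out 1 library, PLX5622 male 2 included. The limma camera adjusted p in these fits were up to 0.0137 for leukocyte adhesion and 0.0468 for venous genes.

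Camera called 14 of 39 lists between the diets, and the other 59 splits of the samples within the sexes called 2 to 11, with a median of 5. Of the remaining called lists, angiogenic tip cell genes were higher at a limma camera adjusted p of 0.00048, where Angpt2 rose and 16 members did not pass. Glycolysis (0.00149), pericyte (0.0208), antigen presentation (0.0294) and cell cycle genes (0.0434) were called higher and smooth muscle genes (0.00335) lower at these limma camera adjusted p, with no member past limma's threshold over all genes. With an estimated correlation the adjusted p of these 6 lists were 0.154, 0.154, 0.468, 0.494, 0.276 and 0.468. The cell cycle call was lost without control male 1, control male 2, control female 2, PLX5622 female 1, PLX5622 male 1 or PLX5622 male 3 (limma adjusted p 0.0504 to 0.154). That of antigen presentation was lost without control male 3, control female 2, PLX5622 female 2, PLX5622 male 1 or PLX5622 male 3 (limma adjusted p 0.0504 to 0.344), and that of pericytes without control female 1, PLX5622 female 1 or PLX5622 male 3 (limma adjusted p 0.0751 to 0.265). The smooth muscle call was lost without control female 1 (limma adjusted p = 0.0718).

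The other lists were not called, with no member past limma's threshold over all genes. Their limma camera adjusted p were 0.112 for platelets, 0.121 for ependyma and choroid plexus, 0.14 for Notch, 0.214 for capillary genes, 0.27 for kinase targets of CSF1R inhibitors, 0.349 for immediate early genes of dissociation and for basement membrane, and 0.392 for TGF-beta and BMP signalling. They were 0.536 for arterial genes, 0.564 for astrocytes, 0.569 for fibroblasts, 0.589 for blood leukocytes, 0.688 for border macrophages, 0.708 for the unfolded protein response, 0.859 for pan-endothelial genes, and 0.903 for xenobiotic response, oxidative phosphorylation, oligodendrocyte precursors and Y-linked genes. For oligodendrocytes and neurons they were 0.939 and 0.94. Some of these passed when a library was left out. Ependyma and choroid plexus did so without control male 1 (limma adjusted p = 0.00315), PLX5622 female 2 (0.0246) or PLX5622 male 3 (0.00576), Notch without control male 3 (0.0152), platelets without PLX5622 female 2 (0.0327), and basement membrane and astrocytes without PLX5622 male 3 (0.00755 and 0.00576). Median, mean and test differed in sign for 5 lists, namely dissociation, unfolded protein response, oligodendrocytes, neurons and transporters.

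No gene was called for a difference in its response to the diet between the sexes. The interaction term of limma called 0 of 12751 genes, with a smallest adjusted p of 0.55 and 312 genes at an unadjusted p under 0.05, and voom on recovered reads also called 0. In limma's model of all 10 libraries, which shares the spread over both sexes, the diet contrast within males called 4 genes and that within females 0, with 614 at an unadjusted p under 0.05 in females, where only 2 mice stood on each diet. Separate limma fits to the libraries of a single sex called 8 genes in males and 0 in females, with 502 at an unadjusted p under 0.05 in females. All 17 genes called over both sexes had the same sign in each. That follows from diets that did not overlap for these genes, so it does not test whether the sexes respond alike. Sqle was at 1.07 in males and 0.64 in females. Across all tested genes, which are not independent replicates, the fold changes of the sexes had a Pearson r of 0.163 and a Spearman rho of 0.207.

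Between the sexes 8 genes passed, all of them on the sex chromosomes. The X-linked genes Kdm6a, Kdm5c, Ddx3x and Eif2s3x were higher in females by 0.62 to 0.81 on the log2 scale, and limma's adjusted p was 0.0106 for Kdm6a and lower for the others. The Kdm6a call was lost without control female 2 or PLX5622 female 2 (limma adjusted p = 0.0585 and 0.0767), with no filter on low values (0.063), and without the males numbered 3 (0.0785) or 2 (0.0545) of both diets. Eif2s3y, Ddx3y, Kdm5d and Uty, which are Y-linked, were higher in males. Xist, the RNA of the inactive X, lay between 62.9 and 107 TPM in the 4 female libraries and at most 0.099 TPM in the 6 male ones, so each library matched its sex in the titles. Xist was not among the tested genes. The filter asks for at least 5 libraries, which a gene present only in the 4 female ones cannot reach.

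The authors' deposited table held 116 genes at an adjusted p under 0.05 in DESeq2, 52 higher and 64 lower on PLX5622, out of 19474. Of these 80 were tested here on TPM, all 80 with the same sign and an unadjusted limma p under 0.05, and 16 were called in both. The other 36 lay below the filter on TPM used here, 35 of them lower on PLX5622. The authors' deposited table counted 19 of the microglial list among its calls, and gave Sqle a log2 fold change of 0.98 and Csf1r one of -5.95. Across the 12749 genes in both, which are not independent replicates, the log2 fold changes had a Pearson r of 0.945 with those of limma.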

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

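All tests of explanations in this part were chosen after the results were seen. A library of either diet was singled out where its gap to the nearest of the 4 others exceeded the 95% limit of Dixon's test. That happened in 18 of 211 groups of values (8.53%), and chance gives about 5% for values fixed beforehand. Some of these genes were named after their values were seen, so the share cannot be set against chance.

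Control female 1 held almost no microglial RNA, and its Mylip stood at 37.7 TPM against 44.9 to 46.9 in the other controls. A sample from the PLX5622 diet under a wrong label is argued against, since 0 of the 7 genes higher on PLX5622 in a fit without this library lay past the midpoint towards PLX5622 in it. Low depth is argued against as well. At the rate of the other controls, its 31.9M reads would hold 2435 reads of 19 untested microglial genes, and 89 were found (3.66%). A cleaner sort of this sample stays open and was not tested, and no biological explanation was tested.

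PLX5622 female 2 had a smaller rise of the cholesterol enzymes, with Fdps at 81.5 TPM against 105 to 113 in the other PLX5622 libraries, and Abcg1 at 14.1 TPM against 6.73 to 7.74. A wrong label on a control sample is argued against, since 8 of the 12 genes called in a fit without it lay past the midpoint towards PLX5622, and so is depth, at 29.3M reads where another PLX5622 library had 26.4. Mixed-in control RNA that carries microglial transcripts is argued against, since the shares that placed most genes began at 26%, which would bring at least 323 reads of 19 untested microglial genes at the rates of the controls other than control female 1, and 87 were found, against 61 to 88 in the other PLX5622 libraries. RNA of a control with almost no microglial RNA, like control female 1, may explain part of it. The best single share placed 7 of 12 genes, while Rgs10 needed at most 26% control RNA and Abcg1 at least 67%. Such mixing alone therefore did not account for every gene. As a part of the cause it cannot be told apart from a weaker response. Its H2-K1 was 1600 TPM against 1200 to 1290, and a weaker response of this mouse was not tested.

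The falls of Rgs10, Snord16a, Abcg1 and Scn3b on PLX5622 could reflect loss of microglial RNA carried over in the sort. Control female 1, with almost no microglial RNA, lay 0.344 of the way to PLX5622 for Rgs10, 0.191 for Snord16a, 0.032 for Abcg1 and -0.052 for Scn3b. These shares were measured from the mean of the other controls, most of them male. Control female 2, with 671 Csf1r reads against 3, held 44 Rgs10 reads in 36.1M, and control female 1 held 43 in 31.9M. The log2 fold change of Rgs10 was -1.89 in males and -0.81 in females. Its share therefore need not reflect missing microglial RNA. A share near 1 would fit carried-over RNA and a share near 0 a fall in the endothelial cells, but 1 library alone cannot tell these apart. In the other controls Csf1r ran from 6.78 to 20.2 TPM, while Abcg1 stayed within 15.1 to 17.3 TPM and Scn3b within 10.6 to 12.5. On PLX5622 Abcg1 was 6.73 to 14.1 TPM and Scn3b 5.16 to 7.63. These values argue against carried-over RNA as the whole of the fall of Abcg1 and Scn3b. For Rgs10 and Snord16a it stays open. A direct effect of the drug on endothelial cells and an effect of microglial loss cannot be separated by this design.

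The other libraries that stood apart are given as values. In PLX5622 male 2, Lcn2 was 92.5 TPM (others of its diet 5.0 to 14.4), Vcam1 104 (40.4 to 47.0), Ackr1 80.5 (0.473 to 4.68), and the mean centred log2 level of leukocyte adhesion genes 0.727 (-0.0278 to 0.106). In control male 3, Ctnnb1 was 1450 TPM (1650 to 1690) and Tgm2 342 (388 to 396). Bst2 was 439 TPM in PLX5622 female 1 (335 to 364). In PLX5622 male 3, Pcna was 739 TPM (544 to 597) and the level of basement membrane genes -0.234 (0.0607 to 0.103). In control female 2 the levels were 0.118 for Wnt genes (-0.01 to 0.02), 0.133 for capillary genes (-0.000723 to 0.0267) and 0.0461 for TGF-beta and BMP genes (-0.0376 to -0.0208). The oligodendrocyte level of control male 1 was 0.42 (-0.222 to -0.066), and control male 2 held 61.5M reads (28.1 to 36.1).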

How the results depend on the processing

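Of the alternatives, 29 were planned and 6 were chosen after seeing the data, namely voom with either filter, the batch term and the 3 fits without a pair of libraries. The 17 genes called between the diets kept their sign in every alternative that tested them. Their number was 7 with no filter on low values (7 higher, 0 lower), where more genes are tested, 8 in a separate fit of males only (3 and 5), 0 in one of females only (502 at an unadjusted limma p under 0.05), where fewer samples remain, and 5 at an adjusted limma p under 0.01. It was 6 without control male 3 and PLX5622 male 3, 0 without PLX5622 male 2 and control male 2 (761 unadjusted), and 5 to 16 with 1 library left out. The cause was not tested beyond the smaller number of samples. Apart from these and the replicate block, the settings gave 15 to 23 genes, with 21 in voom on recovered reads. The 14 lists became 0 with an estimated correlation, 1 with fry's directional test and 10 with its mixed test, and 11 to 17 otherwise. The interaction gave 0 genes in each alternative run and the sex comparison 7 to 9. The authors' deposited table held 62 genes at an adjusted p under 0.01 in DESeq2. Depth of 26.4 to 61.5M reads limits low genes most.

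With a replicate block, 11 genes were called (9 higher, 2 lower), 9 of them among the 17, and 14 lists. Whether the numbers pair samples is not given in the labels, and the data do not settle it, so the main fit used no block. The deviations of same-numbered males 1, 2 and 3 correlated at 0.121, 0.031 and 0.19. With another number the highest correlations were 0.083, 0.032 and -0.093, so males 1 and 3 correlated better with their own number. Females gave 0.157 against -0.157, which 2 females per diet force to be equal and opposite.

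Over the settings tried, libraries left out included, the limma camera call was lost in 11 for cell cycle, 8 for antigen presentation, 7 for Wnt, 6 for pericytes, 2 for smooth muscle and 1 for caveolae. With the sign kept, a call was gained in 5 each for junctions and ependyma, 3 each for Notch and platelets, 2 for basement membrane and 1 each for astrocytes, border macrophages, capillary genes and oxidative phosphorylation. The cause was not tested.

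The sign turned for the following log2 fold changes and list medians, in which only oxidative phosphorylation passed its test in either fit, without control female 1 and PLX5622 female 2 (limma camera adjusted p = 0.0423). The cause was not tested. With median-of-ratios scaling these were Cavin2 0.0041, Rgs5 0.0054 and oxidative phosphorylation 0.0041. With quantile normalization they were Pecam1 -0.0096 and transporters 0.010, with no filter blood leukocytes -0.0015, with a mean TPM of at least 5 cholesterol efflux 0.044, and with sample weights B2m -0.034. In males only they were Acly -0.010, Apcdd1 0.0044, Cxcl12 0.034, Mcm6 0.020, Notch -0.0051, unfolded protein response 0.0044 and neurons 0.080. In females only they were Nfkbia 0.034, Rgs5 0.027, fatty acid synthesis -0.081, dissociation -0.0029, astrocytes -0.014, oligodendrocytes 0.14, neurons 0.026 and Y-linked genes 0. With voom they were Cavin2 0.0059, Rgs5 0.0057 and oxidative phosphorylation 0.0031, and with a mean of at least 10 reads Cavin2 0.0057, Rgs5 0.0058, oxidative phosphorylation 0.0032, blood leukocytes -0.13 and oligodendrocytes 0.18. Without control female 1 and PLX5622 female 2 they were Acly -0.011, Notch -0.012, basement membrane -0.0055, oxidative phosphorylation 0.035 and blood leukocytes -0.19. Without the males numbered 3 they were Nfkbia 0.0099 and B2m -0.089. Without the males numbered 2 they were Acly -0.058, fatty acid synthesis -0.062, TGF-beta -0.0049, basement membrane -0.0056, oxidative phosphorylation 0.019, astrocytes -0.081, oligodendrocytes 0.024 and Y-linked genes -0.046.

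With 1 library left out at a time, the following ran from their lowest to their highest value. Among genes, Acly ran from -0.031 to 0.078, Apcdd1 -0.11 to 0.0070, B2m -0.053 to 0.11, Cavin2 -0.049 to 0.018, H2-K1 -0.0050 to 0.12, Pecam1 -0.0041 to 0.024, Rgs5 -0.13 to 0.090 and Tgm2 -0.095 to 0.030. Among list medians, transporters ran from -0.035 to 0.0042, TGF-beta -0.017 to 0.037, Y-linked genes -0.028 to 0.053, astrocytes -0.11 to 0.17, basement membrane -0.016 to 0.095, cholesterol efflux -0.069 to 0.0026, fatty acid synthesis -0.057 to 0.12, neurons -0.19 to 0.063, oligodendrocytes -0.046 to 0.013, oligodendrocyte precursors -0.18 to 0.029, oxidative phosphorylation -0.052 to 0.029 and the unfolded protein response -0.056 to 0.014.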

Other observations

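All tests in this part were chosen after the results were seen. Of 39 lists, camera called 7 between the sexes over both diets. Interferon response genes were higher in females. All 29 members lay above 0, with a median log2 difference of 0.30 (limma camera adjusted p = 3.10e-29, and adjusted p = 0.159 with an estimated correlation), and none passed limma by itself. This call held with each library left out. Y-linked genes were lower in females (limma adjusted p = 8.31e-47, and adjusted p = 0.00108 with an estimated correlation). Arterial (median -0.11), microglial (-0.26), oxidative phosphorylation (-0.05) and glycolysis genes (-0.06) were also called lower in females and basement membrane genes (0.13) higher, at limma camera adjusted p of 0.00658, 0.00658, 0.00678, 0.0312 and 0.0312, and adjusted p of 0.485 to 0.912 with an estimated correlation. The microglial call was lost without control female 1 (limma adjusted p = 0.69, median -0.07) or control male 3 (0.0978), and the arterial call without control female 2 (0.13). That of oxidative phosphorylation was lost without control male 2, control female 2, PLX5622 female 2 or PLX5622 male 3 (limma adjusted p 0.0879 to 0.763). That of basement membrane was lost without control male 3, control female 2, PLX5622 female 1, PLX5622 female 2 or PLX5622 male 3 (limma adjusted p 0.0728 to 0.332). The glycolysis call held only without control male 1, PLX5622 female 2 or PLX5622 male 1 (limma adjusted p up to 0.17 in the other fits). The response of interferon response genes to the diet was also called for a difference between the sexes, with a median log2 fold change of 0.29 in males and 0.09 in females (limma camera adjusted p of the interaction = 9.99e-07, and adjusted p = 0.942 with an estimated correlation). Microglial genes (-1.22 in males, -0.43 in females) and Notch genes (-0.0051 and 0.14) were called for the interaction at a limma adjusted p of 0.042, and both had an adjusted p of 0.942 with an estimated correlation. Control female 1, which held almost no microglial RNA, is 1 of the 2 control females.

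Other splits of the 10 samples were tried to see whether chance gives as many calls. For the diets, 1 of 60 splits within the sexes, the real one, gave as many as 17 genes, and the highest of the others gave 6. Chance is excluded at the 5% level for a count of 17. For the lists 1 of 60 gave as many as 14, and the highest other gave 11, so chance is excluded at the 5% level for a count of 14 only. Each of the other 59 splits called 2 or more lists, with a median of 5, so the count does not show that each of the 14 lists differs between the diets. For the sexes 2 of 100 splits within the diets gave as many as 8 genes, the highest other giving 32, so chance is excluded at the 5% level there too. That split set the last-numbered sample of each group (control male 3, PLX5622 male 3, control female 2 and PLX5622 female 2) against the rest, which points to a structure of the samples that is balanced over the diets. With it as a batch term, 19 genes were called between the diets, 17 of them shared, with 14 lists and 9 sex genes.

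In mean centred log2 levels over lists, exact permutation over 252 splits can give no two-sided p under 0.00794, which cholesterol biosynthesis, cholesterol uptake and leukocyte adhesion reached, with an adjusted p of 0.103 over 39 lists, so that no list passed this test. These splits ignored sex, which was in the main model and by which the interferon list differed. A high p in them therefore does not argue against an effect of the diet. Of the other lists called by camera between the diets, cell cycle had an exact permutation p of 0.0238, venous 0.0317 and microglia 0.0476. It was 0.111 for smooth muscle and for glycolysis, 0.119 for angiogenic tip cells, 0.135 for pericytes, 0.143 for interferon response, 0.262 for Wnt, 0.413 for caveolae and 0.548 for antigen presentation. Adjusted over all 39 lists, the exact permutation p of these 11 ran from 0.232 to 0.763.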
